A study of Homo sapiens with 40 samples.

How the data were processed

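Whole blood from 20 farmworkers and 20 other manual workers was collected into PAXgene tubes, which stabilise RNA, per the labels' protocols. Total RNA was incubated with oligomers that pair with alpha and beta globin mRNA and block its reverse transcription, and the product was labelled with biotin, again per the labels. Each sample was hybridised to 1 Affymetrix Human Genome U133 Plus array, on which a probe set is a group of short probes against 1 transcript. The deposited values are log2 expression levels made with RMA, per the submitters' processing notes. RMA corrects the background, brings the arrays to a shared distribution and summarises the probes of each set. Its version and settings are not given in the sources used here, nor is it stated whether all 40 arrays were normalized together.

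The value table held 54675 probe sets for each of the 40 samples, including 62 control probe sets. The lowest deposited value was 2.65 and the highest 15.2, and array medians lay between 6.28 and 6.39 on the log2 scale. No 2 columns held identical values. Pairwise correlations between arrays over the kept genes ranged from 0.866 to 0.991, with a median of 0.976. Arrays give no count or depth, so the number of arrays limits the precision.

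Probe sets were named through the platform annotation, with symbols brought up to date through the gene identifier. Of the probe sets other than controls, 41091 named 1 gene, 1801 named several genes and 11721 had no gene name in the table used here. No gene was named from a probe set with several genes. A gene was represented by its probe set with the highest mean over all 40 samples, which gave 19775 genes. A gene was kept if its value lay above the median of its array in at least 20 samples, which left 12280 genes. Among 687 called genes with more than 1 kept probe set, all kept probe sets of 571 genes had the same sign of change.

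Groups were taken from the occupation given in the labels. The series calls the manual workers matched, but the labels do not pair a farmworker with a manual worker, so the groups were compared without pairing. The main test was a linear model per gene with moderated standard errors in limma (version 3.58.1, R version 4.3.3), with Benjamini-Hochberg adjustment over the 12280 genes and a threshold of 0.05. Log2 fold changes are farmworker minus manual worker. P-values measure the spread between these samples.

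The design, the alternatives, 42 gene lists and the rule for named genes were fixed before the data were examined, apart from those said to be chosen later. Of the lists, 14 held markers of blood cell types and 28 held pathways and complexes. Lists with at least 5 kept members, 40 in all, were tested with limma's camera at a preset correlation between genes of 0.01. Camera asks whether a list stands apart from the other genes. Camera with an estimated correlation and fry, which asks only whether the members of a list move one way on balance, were run beside it. List p-values without such a remark, in the other settings too, rest on the preset correlation. The estimate was far above it, at 0.79 for the erythroid list and 0.68 for the platelet list. Named genes are the 15 largest rises and the 15 largest falls among called genes, up to 4 members of each described list with the smallest p, and every kept member of the cholinesterase and paraoxonase list. XIST and Y-linked genes were left out by rule, as were clone names.

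Spiked control transcripts, 3 prime and 5 prime control probe sets and 5 manual worker arrays that carry a mark in the labels were tested as separate questions. A cell type score is the mean standardised level of a list's kept members in a sample. Arrays were said to stand apart if their median correlation with the other arrays lay more than 3 median absolute deviations below the median of all arrays, a limit of 0.970. This applied to 8 arrays, 6 from farmworkers and 2 from manual workers, and was chosen after seeing the data. Permutation tests of single measures were two-sided with 100000 resamples.

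Alternatives covered the filter on dim genes, the choice of probe set, repeated normalization, variance models, array weights, the marked arrays, array order, RNA quality, cell type scores, a rank test and leaving out each sample. The gene test was tried on simulated data in which 200 of 12280 genes were changed. At true log2 changes of 0.25, 0.5 and 1, it recovered 55.2%, 82.1% and 98.5% of them, and 12 of 169 calls were false. The simulated genes varied independently, with the same SD in both groups. These shares therefore do not describe correlated genes or genes of unequal spread.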

Results

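Gene expression was measured in whole blood of 20 farmworkers and 20 manual workers in other jobs, with 1 array for each sample. The study's title asks about expression signatures of pesticide exposure. No exposure measurement was used here, so occupation was the contrast.

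In blood of farmworkers 14 of 17 red cell genes and 3 of 12 neutrophil granule genes fell, and 6 of 21 genes of Toll-like receptors and the inflammasome rose. The lists passed in camera at the preset correlation (adjusted p = 0.611, 0.629 and 0.611 with an estimated correlation). TRIM58, a ubiquitin ligase of late red cell development, was 2.61-fold lower in farmworkers, at 10.56 ± 1.38 against 11.95 ± 0.45 (log2, mean ± SD, n = 20 and 20). LY96, which encodes the MD-2 partner of Toll-like receptor 4, was 2.22-fold higher, at 8.96 ± 1.35 against 7.81 ± 0.42. In limma, 581 genes were higher and 871 lower in farmworkers, 11.8% of the 12280 tested. Most changes were small, with a median absolute log2 fold change of 0.24 (1.18-fold) among the called genes. An absolute log2 fold change above 0.5 was reached by 91 of the higher and 117 of the lower genes. Without the 8 arrays that stand apart, limma called 71 higher and 28 lower genes. Every manual worker array precedes every farmworker array in the numbering, so array order and group cannot be told apart. With array order as a covariate 0 genes were called.

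The largest rise was that of EVI2A, a membrane protein gene that lies within an intron of NF1, with a log2 fold change of 1.44 ± 0.46 (SE; limma adjusted p = 0.0368). LY96 rose by 1.15 ± 0.31 (adjusted p = 0.0151), and 17 of 20 farmworkers lay above the manual workers' median. RGS18, a regulator of G protein signalling found in platelets and myeloid cells, rose by 1.03 ± 0.30 (adjusted p = 0.0245). Mitochondrial genes among the largest rises were COXFA4 (formerly NDUFA4), a cytochrome c oxidase subunit, at 1.02, and UQCRQ, a complex III subunit, at 0.88. CLC, which encodes the Charcot-Leyden crystal protein of eosinophils and basophils, rose by 0.93 ± 0.24 (adjusted p = 0.013). S1PR3, a sphingosine 1-phosphate receptor, rose by 0.86 ± 0.14 (adjusted p = 0.0013), above the manual workers' median in 19 of 20 farmworkers. The other kept probe set of S1PR3 had the opposite sign, and the mean of its probe sets rose by 0.37. The other genes of largest rise were MCTP1 (0.99), the actin capping gene CAPZA2 (0.93), LYSMD3 (0.87), the lipid transfer gene OSBPL8 (0.86), the G protein subunit gene GNG10 (0.83), the glycolipid enzyme gene B3GNT5 (0.81), GASK1B (0.79) and ZNF267 (0.78). As the mean of their probe sets, MCTP1 rose by 0.70, CAPZA2 by 0.68, OSBPL8 by 0.51 and GASK1B by 0.48. Without the 8 arrays that stand apart from the rest in overall correlation, 6 of them from farmworkers, EVI2A had a value of 0.40 (adjusted p = 0.403) and LY96 of 0.43 (adjusted p = 0.151). Among these 15 genes only S1PR3 still passed (0.69, adjusted p = 0.0278). Without the marked arrays EVI2A (1.52, adjusted p = 0.0636), COXFA4 (1.08), UQCRQ (0.94), LYSMD3 (0.94) and ZNF267 (0.80) lost their calls, with values no smaller than before.

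The largest fall was that of EIF5A, a translation factor, with a log2 fold change of -1.47 ± 0.42 (adjusted p = 0.0226). Its size depended on the probe set, as the mean of its probe sets changed by -0.93, less than the -1.38 of TRIM58 in that setting, and without the marked arrays it did not pass (-1.25, adjusted p = 0.079). ERAP2, an aminopeptidase that trims peptides for MHC class I, changed by -1.31 ± 0.38 (adjusted p = 0.0239), below the manual workers' median in all 20 farmworkers, and by -0.68 as the mean of its probe sets. SLC6A8, the creatine transporter, changed by -1.24, and GMPR, an enzyme of purine metabolism, by -1.20. Red cell genes made up much of the rest: EPB42, which encodes protein 4.2 of the red cell membrane skeleton, at -1.17, KLF1, the erythroid transcription factor, at -1.13, and SLC4A1, the band 3 anion exchanger, at -1.08. Globin genes fell as well, HBD by 1.10 and HBQ1 by 1.06 on the log2 scale. SELENBP1 (-1.18), which is also in the erythroid list, TNS1 (-1.15), the granule protein gene LTF (-1.14), ABCC13 (-1.12) and the noncoding STX17-DT (-1.04) completed the group. STX17-DT changed by -0.52 as the mean of its probe sets. Without the 8 arrays that stand apart, TRIM58 had a value of -0.64 (adjusted p = 0.0817), ERAP2 of -1.48 (adjusted p = 0.066) and EIF5A of -1.18 (adjusted p = 0.163), and none of the 15 genes passed. Besides EIF5A, the calls of SELENBP1 (-1.15), TNS1 (-1.13), HBD (-0.93) and SLC4A1 (-1.05) were lost without the marked arrays (adjusted p = 0.0528, 0.0707, 0.123 and 0.062).

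**Figure D1:**
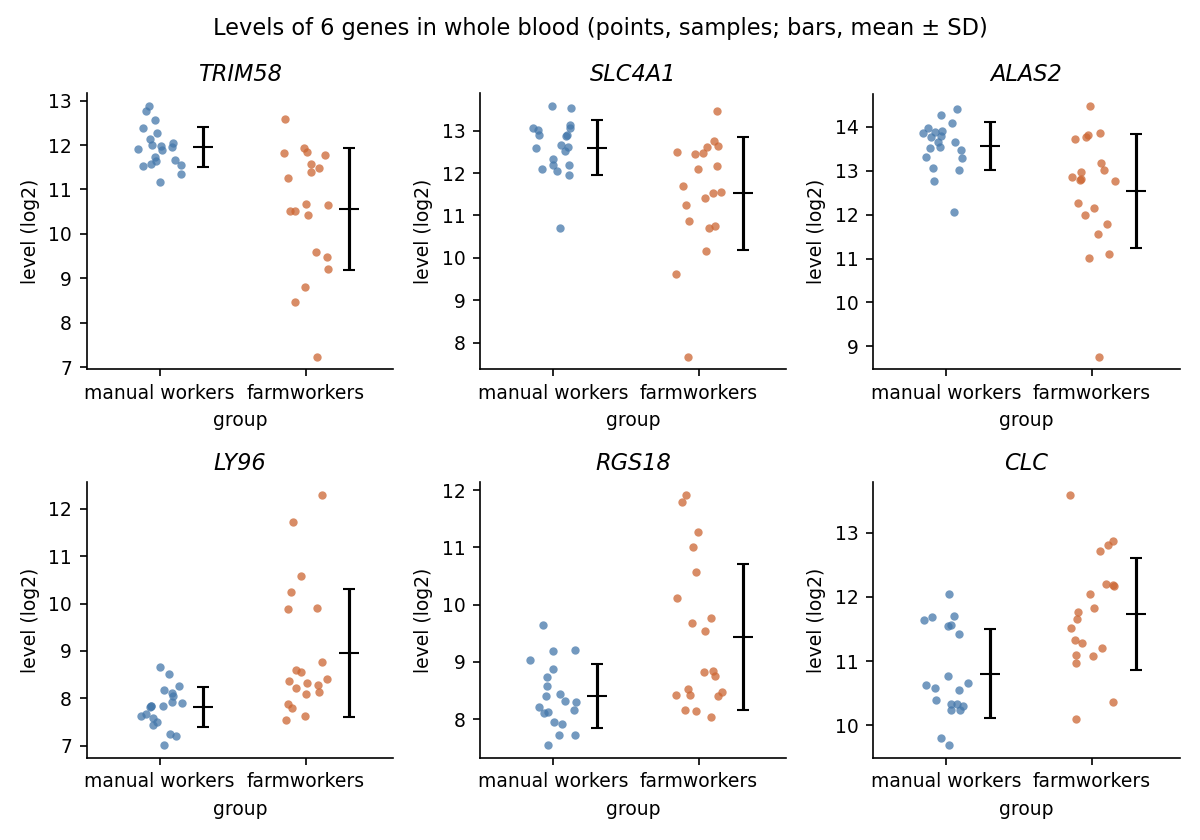
Levels (log2) of 6 genes in each sample of the manual workers and the farmworkers, with 1 point for each of 20 samples per group and bars for the mean ± SD. TRIM58, SLC4A1 and ALAS2 had lower means in farmworkers and LY96, RGS18 and CLC higher ones, and the SD of TRIM58 was 1.38 in farmworkers against 0.45 in manual workers.

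Of 17 kept members of the erythroid and reticulocyte list, 14 fell, 0 rose and 3 did not pass the test, and 15 fell when adjusted over the list alone. The mean log2 fold change was -0.89 (camera adjusted p = 2.17e-09; adjusted p = 0.611 with an estimated correlation). TRIM58 (-1.39), the globin gene HBM (-1.01), the survival gene BCL2L1 (-0.74) and the membrane skeleton gene DMTN (-0.94) had the smallest p-values. HBB, the kept member of the alpha and beta globin list, fell by 1.01, and its transcript was one of those blocked during labelling. The erythroid score per sample was lower by 0.897 in farmworkers (permutation adjusted p = 0.0077). Leaving out the 8 arrays that stand apart brought the mean of the erythroid list to -0.37, with camera adjusted p = 1.71e-04 at the preset correlation. The calls of TRIM58 (-0.64), HBM (-0.53), BCL2L1 (-0.31) and DMTN (-0.35) were lost there (limma adjusted p = 0.0817, 0.1245, 0.2351 and 0.253).

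Platelet and megakaryocyte markers were lower on average, with a list mean of -0.32 (camera adjusted p = 0.0036; adjusted p = 0.674 with an estimated correlation). Of 16 members, 1 fell and 15 did not pass the test, and 1 fell when adjusted over the list alone. That member was NRGN (neurogranin), at -0.47 ± 0.14 (adjusted p = 0.028). CLU, which encodes the platelet granule protein clusterin, had a log2 fold change of -0.54 (adjusted p = 0.0558). SPARC (-0.42) and the clotting factor gene F13A1 (-0.30) were also short of the threshold. The platelet score per sample differed by -0.507 and did not pass (permutation adjusted p = 0.101). Without the 8 arrays that stand apart the list mean was -0.17 and no longer past the threshold (adjusted p = 0.186), and NRGN had a value of -0.27 (adjusted p = 0.313). With array order as a covariate the list mean turned to 0.22 (camera adjusted p = 0.0069 at the preset correlation).

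The immature neutrophil granule list had a lower mean in farmworkers and the mature neutrophil list a higher one. In the granule list 3 of 12 members fell, 0 rose and 9 did not pass, and 7 fell when adjusted over the list alone. The list mean was -0.83 (camera adjusted p = 1.67e-04; adjusted p = 0.629 with an estimated correlation). LTF (lactoferrin) fell by 1.14, LCN2 (lipocalin 2) by 0.98 and CEACAM6 by 0.94, while DEFA4, a defensin gene, had a value of -1.14 that did not pass (adjusted p = 0.0574). In the neutrophil list 3 of 18 members rose, 15 did not pass, and 5 rose when adjusted over the list alone. Its mean was 0.26 (camera adjusted p = 0.0011; adjusted p = 0.674 with an estimated correlation). The vanin genes VNN2 (0.52) and VNN3P (0.55) and the chemokine-like PROK2 (0.52) rose, and the Fc receptor gene FCGR3B had a value of 0.28 (adjusted p = 0.0585). The neutrophil score per sample was higher by 0.491 in farmworkers but did not pass (permutation adjusted p = 0.101). None of these genes passed without the 8 arrays that stand apart: LTF was at -0.93, LCN2 at -0.73, CEACAM6 at -0.56, VNN2 at 0.32, VNN3P at 0.46 and PROK2 at 0.54 (adjusted p = 0.13, 0.163, 0.259, 0.322, 0.117 and 0.075). Leaving out the marked arrays brought the neutrophil list mean to 0.17 (adjusted p = 0.0211), and VNN2 (0.44, adjusted p = 0.0991) and PROK2 (0.46, adjusted p = 0.0719) lost their calls.

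Monocyte and innate sensing lists had higher means in farmworkers. In the monocyte list 3 of 13 members rose and 10 did not pass, and 5 rose when adjusted over the list alone, with a mean of 0.21 (camera adjusted p = 0.0011; adjusted p = 0.611 with an estimated correlation). These were the protease gene CTSS (0.35, adjusted p = 0.0057), the carboxypeptidase gene CPVL (0.31) and the beta-glucan receptor gene CLEC7A (0.21), while VCAN had a value of 0.25 (adjusted p = 0.0833). The monocyte score per sample was higher by 0.571 in farmworkers (permutation adjusted p = 0.0101). In the Toll-like receptor and inflammasome list 6 of 21 members rose, 0 fell and 15 did not pass, and 10 rose when adjusted over the list alone. Its mean was 0.29 (camera adjusted p = 5.97e-06; adjusted p = 0.611 with an estimated correlation). Besides LY96, these included CASP1, the protease that matures interleukin 1 beta, at 0.38 ± 0.09 (adjusted p = 0.0108), TLR8 at 0.46 ± 0.12 (adjusted p = 0.0118) and TLR6 at 0.38 ± 0.10 (adjusted p = 0.0189). TLR8 lay above the manual workers' median in all 20 farmworkers. The Toll-like list moved with the cell markers: with cell type scores as covariates its mean was 6.4e-05 (adjusted p = 0.894), and with array order 0.08 (adjusted p = 0.141). When the 8 arrays that stand apart were left out, CTSS (0.27) and TLR6 (0.38) still passed, while CASP1 (0.21, adjusted p = 0.195), TLR8 (0.33, adjusted p = 0.0799), CPVL (0.24, adjusted p = 0.153) and CLEC7A (0.15, adjusted p = 0.199) did not. CPVL (0.29, adjusted p = 0.0656) and CLEC7A (0.18, adjusted p = 0.0631) also lost their calls without the marked arrays. In the NF-kappaB and TNF inflammatory response list, which did not pass (camera adjusted p = 0.123), 2 of 16 members rose and 4 rose when adjusted over the list alone. They were the cytokine gene IL1A (0.44, adjusted p = 0.004) and PTGS2, which encodes cyclooxygenase 2 (0.69, adjusted p = 0.0343), while TNFAIP6 (0.53) and BCL2A1 (0.88) did not pass.

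Genes responsive to glucocorticoids had a mean of 0.18 (camera adjusted p = 0.0099; adjusted p = 0.611 with an estimated correlation). Of 13 members, 2 rose, the kinase gene SGK1 (0.38) and the adenosine receptor gene ADORA3 (0.48), and both rose when adjusted over the list alone. The phosphatase gene DUSP1 (0.30, adjusted p = 0.0767) and the decoy receptor gene IL1R2 (0.34, adjusted p = 0.0957) did not pass. With cell type scores as covariates the list mean was 0.08 (adjusted p = 0.0849), and with array order 0.13 (adjusted p = 0.0796). SGK1 (0.34, adjusted p = 0.0531) and ADORA3 (0.38, adjusted p = 0.191) lost their calls without the 8 arrays that stand apart.

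Respiratory chain and proteasome lists had slightly higher means in farmworkers, with few members past the threshold. In the oxidative phosphorylation list 4 of 31 members rose, 27 did not pass, and 4 rose when adjusted over the list alone, with a mean of 0.22 (camera adjusted p = 0.0025; adjusted p = 0.674 with an estimated correlation). These were COXFA4, UQCRQ, the oxidase subunit gene COX5B (0.20, with 3 of 4 kept probe sets in this direction) and the ATP synthase subunit gene ATP5PF (0.45). COX5B turned to -0.031 without shared-sequence probe sets (limma adjusted p = 0.758). In the proteasome list 2 of 23 members rose, PSMB3 (0.16) and PSMA7 (0.18), and 1 rose when adjusted over the list alone. PSMB7 (0.15, adjusted p = 0.0619) and PSMC6 (0.59, adjusted p = 0.0999) did not pass. The mean was 0.13 (camera adjusted p = 0.0025; adjusted p = 0.629 with an estimated correlation). Without the 8 arrays that stand apart the mean was 0.0065 for oxidative phosphorylation (adjusted p = 0.602) and 0.029 for the proteasome (adjusted p = 0.111). Of the genes named from these lists PSMB3 alone kept its call there (0.18, adjusted p = 0.0448). Without the marked arrays PSMB3 (0.15), ATP5PF (0.48), COXFA4 (1.08) and UQCRQ (0.94) lost theirs (adjusted p = 0.0517, 0.0696, 0.0639 and 0.0721). In the cell cycle list 2 of 14 members fell, the helicase subunit genes MCM2 (-0.25, adjusted p = 0.0108) and MCM4 (-0.17, adjusted p = 0.0486), and both fell when adjusted over the list alone. MCM6 (-0.16) and the thymidylate synthase gene TYMS (-0.35) did not pass. MCM2 (-0.20, adjusted p = 0.126) and MCM4 (-0.18, adjusted p = 0.16) lost their calls without the 8 arrays that stand apart, and MCM4 (-0.12, adjusted p = 0.169) also without the marked arrays. The list mean was -0.15 (camera adjusted p = 0.0048; adjusted p = 0.629 with an estimated correlation). None of 23 ribosomal protein genes passed the test at a list mean of 0.15 (camera adjusted p = 0.139), nor did any of 16 translation factor genes at 0.06 (camera adjusted p = 0.325).

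**Figure D2:**
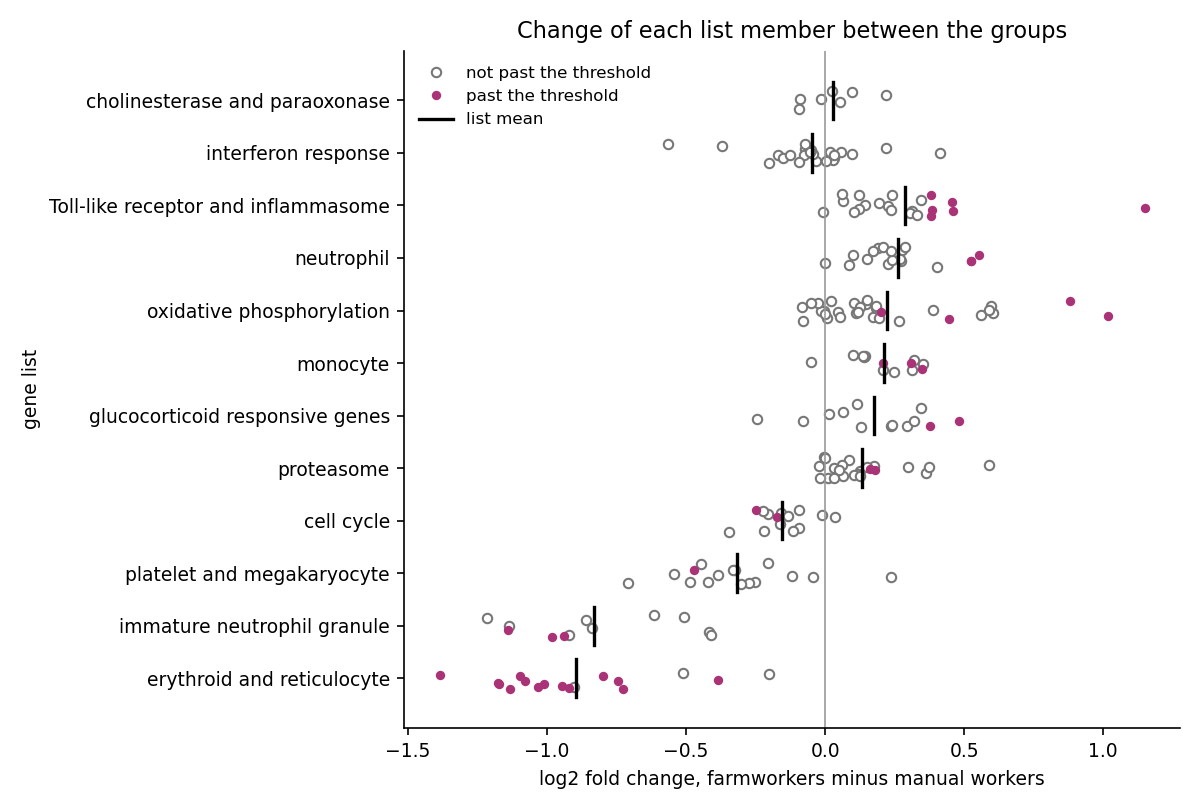
Log2 fold change, farmworkers minus manual workers, of each kept member of 12 gene lists, where filled points passed the threshold of 0.05 and vertical bars mark list means. The erythroid list had a mean of -0.89 with 14 members past the threshold, and the cholinesterase and paraoxonase list a mean of 0.03 with 0.

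Lymphocyte lists did not pass the list test. In the T cell list 3 of 15 members fell (4 when adjusted over the list alone): CD5 (-0.25), CD3E (-0.23) and CD6 (-0.22), all surface proteins of T cells, while CD247 had a value of -0.20 (adjusted p = 0.0776). The list mean was -0.04 (camera adjusted p = 0.233). No member passed among 13 CD8 and cytotoxic cell genes (list mean -0.02), 11 natural killer cell genes (-0.06), 14 B cell genes (0.06), 7 plasma cell genes (-0.12) and 6 basophil and mast cell genes (-0.26), where the smallest camera adjusted p was 0.38. In the eosinophil list CLC alone passed among 10 members (2 when adjusted over the list alone), with a list mean of 0.18 (camera adjusted p = 0.224). In the dendritic cell list IL3RA, an interleukin 3 receptor gene, fell by 0.30 (1 of 8 members; 1 rose and 1 fell when adjusted over the list alone) while CLEC10A had a value of 0.35 (adjusted p = 0.065), at a list mean of -0.03 (camera adjusted p = 0.851).

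Genes of pesticide targets and detoxification were examined because organophosphates inhibit cholinesterases. Only RNA levels were compared, so the values do not show whether enzyme activity differed. Of 10 genes in the cholinesterase and paraoxonase list, BCHE (butyrylcholinesterase), PON1 and PON3 were dropped by the filter on dim genes and not tested. None of the 7 kept genes passed the test, also when adjusted over the list alone, and the list mean was 0.03 (camera adjusted p = 0.891). The acetylcholinesterase gene ACHE had a log2 fold change of -0.09 ± 0.05 (adjusted p = 0.229), at 6.65 ± 0.15 in farmworkers against 6.74 ± 0.17. ACHE was thus dim, little above the array medians of 6.28 to 6.39. The other values were 0.22 for CES1, 0.10 for FAAH, -0.10 for PON2, 0.05 for PNPLA6, 0.03 for APEH and -0.02 for CES2. In the same list, 0 members had an unadjusted p under 0.05, the smallest being 0.0837. The acetylcholine receptor and transport list had 4 kept members, too few for a list test, and none passed. CHRNB2 had the smallest p, with a value of -0.15 (adjusted p = 0.0766).

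CYP1B1, a cytochrome P450 induced through the aryl hydrocarbon receptor, rose by 0.65 ± 0.19 (adjusted p = 0.026), and the receptor gene AHR rose by 0.52 ± 0.15 (adjusted p = 0.0213). Neither passed without the 8 arrays that stand apart, at 0.33 for CYP1B1 (adjusted p = 0.304) and 0.28 for AHR (adjusted p = 0.271), and with array order as a covariate AHR turned to -0.069. CYP1B1 also lost its call without the marked arrays (0.58, adjusted p = 0.0764). In the aryl hydrocarbon receptor list 2 of 6 members rose, and 3 when adjusted over the list alone, with a list mean of 0.26 that did not pass (camera adjusted p = 0.0518). In the cytochrome P450 and conjugation list 3 of 22 members rose, CYP1B1, the acetyltransferase gene NAT1 (0.62) and the glutathione transferase gene GSTO1 (0.23). Adjusted over the list alone, 4 rose and 1 fell, and the list mean was 0.08 (camera adjusted p = 0.325). Among 16 antioxidant enzyme genes MSRB2 (0.38) rose, while PRDX6 (-0.46), PRDX2 (-0.40) and GPX1 (-0.27) fell, and 5 rose and 3 fell when adjusted over the list alone. PRDX2 and GPX1 are abundant in red cells, and 1 kept probe set each of PRDX6 and PRDX2 had the opposite sign. The list mean was 0.06 (camera adjusted p = 0.38). No member passed among 14 NRF2 oxidative stress genes (mean 0.04, camera adjusted p = 0.608) or among 24 interferon response genes (mean -0.05, camera adjusted p = 0.81), also when adjusted over each list alone. IFI27 had a value of -0.57 (adjusted p = 0.155).

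No list kept its call in camera with an estimated correlation, where 1 of 40 lists had an unadjusted p under 0.05, and fry called 5 lists, of which erythroid, monocyte and Toll-like were among the 10 called by camera. With array order as a covariate limma called 0 genes (255 at an unadjusted p under 0.05), with the cell type scores 2, and without the 8 arrays that stand apart 71 higher and 28 lower, while repeating quantile normalization gave 421 higher and 1169 lower genes.

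The question for the controls was whether the arrays differed in control probe sets, which are made to measure spiked transcripts and a few human ones. Spiked bacterial and phage transcripts, which report on hybridisation, had lower means on farmworker arrays in 17 of 18 probe sets, yet none of 63 controls passed the test. Limma gave 6 controls an unadjusted p under 0.05, and the smallest adjusted p was 0.259. The control with that p, AFFX-ThrX-M, lay at 3.79 in farmworkers and 3.87 in manual workers, below the array medians of 6.28 to 6.39. The other Thr, Phe, Lys, Dap and Trpn controls also had means below those medians. Many of the 63 controls may therefore read background alone. The mean hybridisation control level was 11.09 ± 0.21 in farmworkers and 11.18 ± 0.16 in manual workers (permutation p = 0.136). For GAPDH and ACTB, the difference between 3 prime and 5 prime control probe sets, which grows as RNA degrades, was 0.42 ± 0.10 in farmworkers and 0.48 ± 0.16 in manual workers (limma adjusted p = 0.372).

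The first principal component of all kept genes held 41.8% of the variance and followed the hybridisation control level over the 40 samples (Pearson r = 0.762, permutation p = 1e-05, the smallest 100000 resamples can give; Spearman rho = 0.654, p = 5e-05). Within farmworkers r was 0.848 (p = 2e-05; rho = 0.731, p = 4.8e-04) and within manual workers 0.495 (p = 0.028; rho = 0.606, p = 0.0055). Without the 2 samples farthest from the median control level, r was 0.662 over all samples, 0.783 in farmworkers and 0.321 in manual workers, so the size of Pearson's r in manual workers rests in part on those samples. These were among 15 relations, and the adjusted p of Pearson's r was 5e-05, 6e-05 and 0.0467. The component also followed the interquartile range of the array, with r = -0.836 over all samples, -0.843 in farmworkers and -0.815 in manual workers (rho = -0.848, -0.874 and -0.842), and r = -0.777 over all samples without the 2 farthest. The permutation p was 1e-05 over all samples and in farmworkers and 2e-05 in manual workers (adjusted p = 5e-05, 5e-05 and 6e-05). The interquartile range, and the erythroid score given next, come from the same array values as the component. Part of their relation with the component may therefore be built in. The spiked controls are not among the component's genes. For the erythroid score r was 0.594 over all samples (p = 1.4e-04; rho = 0.352, p = 0.0268; r = 0.456 without the 2 farthest; adjusted p = 3.5e-04 for r and 0.0502 for rho, which misses the threshold). Within farmworkers that r was 0.717 (p = 3e-04; rho = 0.752) and within manual workers -0.391 (p = 0.0904; rho = -0.444).

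**Figure D3:**
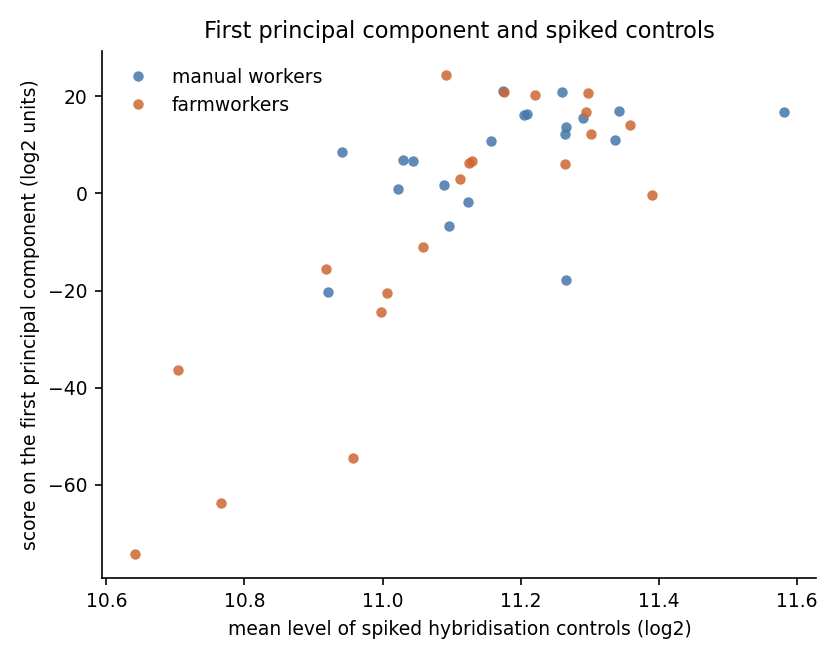
Score of each sample on the first principal component (log2 units) against the mean level of the spiked hybridisation controls (log2), with 1 point for each of 20 manual workers and 20 farmworkers. Low control levels went with low scores (r = 0.762), and the scores had an SD of 29.7 in farmworkers and 11.7 in manual workers.

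In all, 5 manual worker arrays carry a mark in the labels whose meaning is not given, and they were compared with the 15 other manual worker arrays. The largest falls on the marked arrays included ALPL, the neutrophil alkaline phosphatase gene, which changed by -1.28 ± 0.32, and PI3, which encodes the elastase inhibitor elafin, by -1.17 ± 0.24 (limma adjusted p = 0.0432 and 0.0159). The largest rises were those of RALGDS (0.93), the clock gene NR1D2 (0.89) and the epsilon globin gene HBE1 (0.83). Limma called 79 genes higher and 188 lower on the marked arrays. In the neutrophil list 1 member fell, and in the granule and Toll-like lists none passed. The list means were -0.78 for immature neutrophil granules, -0.35 for neutrophils and -0.22 for Toll-like receptors and inflammasome (camera adjusted p = 0.011 for each; adjusted p = 0.827 with an estimated correlation). The basophil and mast cell list (-0.61, 0 members past the threshold) and the glycolysis list (-0.13, 1 member lower) also passed the list test (camera adjusted p = 0.0458; adjusted p = 0.827 with an estimated correlation). The erythroid list had a mean of 0.15 and did not pass (camera adjusted p = 0.441).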

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

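The weighing of array order, whose covariate was itself planned, and the tests of the spiked control level, of the arrays that stand apart, of the platelet list, of the marked arrays' splits and of the probe sets without a single gene were chosen after the results had been seen. The splits of the 40 samples and the tests of RNA quality, marked arrays and cell type scores on the called genes were planned.

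Probe sets that name several genes or none were outside the comparisons above, and they also differed between the groups. Of 5235 such probe sets kept by the filter, 173 were higher and 223 lower in farmworkers, and 1298 had an unadjusted p under 0.05. Among 100 splits of the 40 samples, 1 gave as many, the real one, and the highest other gave 2. Chance is thus argued against here, though 100 splits can give no share below 1 in 100.

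The difference of 1452 genes between the groups was weighed against technical explanations and cell composition. Among 100 splits of the samples 1 gave as many genes, the real one, and the highest other gave 39. Chance is therefore argued against but not excluded, as 100 splits can give no share below 1 in 100. RNA quality is argued against as the cause only as far as the 3 prime to 5 prime difference of GAPDH and ACTB measures it. That difference was 0.42 in farmworkers and 0.48 in manual workers (limma adjusted p = 0.372), so as a covariate it could move the group change little. With it the called genes kept 1.008 times their median absolute log2 fold change (0.996 to 1.02 with any 1 sample left out). RNA quality in other respects was not tested. The marked arrays are argued against likewise, with a ratio of 0.997 without them (0.979 to 1.02). Blood cell composition stays open, as the ratio was 0.592 with cell type scores as covariates (0.511 to 0.65), and these scores are built from genes that differ themselves. Array order and group cannot be told apart, because every manual worker array precedes every farmworker array in the numbering and the covariate raised standard errors 1.88-fold while the ratio fell to 0.462; exposure and other differences between the occupations stay open and untested.

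The lower erythroid list was weighed against a smaller share of red cell RNA alone, the level of the spiked controls and the arrays that stand apart. A smaller red cell share alone would raise the markers of the other cell types alike. Medians were above 0 for neutrophil (0.24), monocyte (0.21), B cell (0.10) and eosinophil (0.08) lists. They were below 0 for platelet (-0.33, SE over members 0.06), immature granule (-0.89), basophil (-0.43) and T cell (-0.12) lists. Natural killer (-0.12), plasma cell (-0.12), CD8 (-0.08) and dendritic (-0.07) medians were also below 0. That SE treats members as independent, though their estimated correlation was 0.68 in the platelet list. Per sample, the platelet score differed by -0.507 and did not pass (permutation adjusted p = 0.101). The platelet mean lost its call without the 8 arrays and turned to 0.22 with array order. Neutrophil and granule lists still moved apart without those arrays (means 0.31 and -0.58). Their means with array order were 0.19 and -1.74. As array order and group cannot be told apart, the values with array order decide nothing here. The spiked control level as the whole cause is argued against, since the list kept 0.855 of its mean with it as a covariate (0.798 to 0.915 with any 1 sample left out). Without the 8 arrays that stand apart the list kept 0.412 of its mean (0.33 to 0.482), so most of the fall may rest on those arrays, which does not tell a property of the array from one of the blood.

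For the marked against unmarked manual worker arrays, 2 of 100 splits into 5 and 15 gave as many as the 267 genes found, the real one included. So large a count was uncommon among the splits. Yet 10 other splits gave some genes, and the highest gave 1496, more than the mark. Chance therefore stays open as an explanation of the 267 genes. The cause of the 1496 genes was not tested.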

How the results depend on the processing

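The settings that use the spiked controls, the interquartile range, the erythroid score alone or leave out the arrays that stand apart were chosen after seeing the data. Of 581 higher and 871 lower genes in the main analysis, both counts stayed within 1.5-fold with no filter, probe set means, no shared-sequence probe sets, repeated normalization, median centring, another variance model, the mark as a block, RNA quality as covariate and a rank test. The counts were 1103 and 1356 with every probe set, 379 and 565 without the marked arrays, and 0 and 0 with array order as covariate. They were 0 and 2 with cell type scores (GPR84, -0.41, and SOCS3, -0.62; 1279 genes at an unadjusted p under 0.05) and 0 and 1 with the erythroid score (APBA2, -0.45; 1366 genes), the 3 genes being named after their values were seen. They were 71 and 28 without the arrays that stand apart, 259 and 341 with the spiked control level and 330 and 547 with the interquartile range as covariate. Lower genes numbered 418 with the 75th percentile filter, where 7372 genes were tested, and 447 with array weights. Leaving out each sample gave 324 to 825 higher and 546 to 1122 lower genes. Apart from fewer genes or samples, the cause was not tested.

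In 3 cases, each a farmworker, leaving out 1 sample moved a count by over 1.5 times, to 324 and 546, 365 and 554, and 381 and 634 genes. All 1452 called genes kept their sign without the marked arrays and without the arrays that stand apart, and 1296 kept it with array order as covariate. As these genes were called on the same samples, kept signs give no separate support. Still called were 807 of them without the marked arrays and 71 without the arrays that stand apart.

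The number of lists past the threshold, 10 in the main analysis, was 0 with an estimated correlation, 5 with fry and 16 with array order. Fry kept 3 of the 10 (erythroid, monocyte, Toll-like), lost the other 7 and added the aryl hydrocarbon receptor and RAS and MAPK lists. With cell type scores, over lists other than cell types, 4 passed, among them 3 of the 5 called without them. With array order, 2 of the 10 lost their call, Toll-like receptor and inflammasome (0.08, adjusted p = 0.141) and glucocorticoid responsive genes (0.13, adjusted p = 0.0796). The cause was not tested. The platelet list mean changed sign with array order as covariate, to 0.22 (camera adjusted p = 0.0069 at the preset correlation). With cell type scores and with the erythroid score alone, the signs of 4 genes turned: SELENBP1 (0.043 and 0.0070), TNS1 (0.066 and 0.11), HBD (0.15 and 0.12) and SLC4A1 (0.016 and 0.035). CLEC7A turned to -0.033 with cell type scores, AHR to -0.069 with array order, and COX5B to -0.031 without shared-sequence probe sets, all short of the threshold. Of 80 named genes followed through the settings, 51 lost their call without the arrays that stand apart, and 18 lost it without the marked arrays. The other 29 stayed on the same side of the threshold without the arrays that stand apart. Of these, only S1PR3, CTSS, TLR6 and PSMB3 had a call in the main analysis to keep. The controls gave 0 calls with and without the marked arrays, and the marked arrays 188 genes with no filter.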

Other observations

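The relations with the erythroid score and the spread on the first component were examined after the results had been seen, while the gene lists were fixed earlier.

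Signalling and cell death genes showed changes in lists that camera did not call. In the RAS and MAPK list 4 of 18 members rose and 0 fell, also when adjusted over the list alone: the exchange factor genes SOS1 (0.62) and SOS2 (0.32), RAB8B (0.60) and the phosphatase gene DUSP6 (0.25). The list mean was 0.13 (camera adjusted p = 0.0758; fry adjusted p = 0.0115). Among 18 apoptosis regulators BID (0.43 ± 0.08, adjusted p = 0.0047), APAF1 (0.40) and MCL1 (0.15) rose and BCL2L1, which is also in the erythroid list, fell by 0.74, at a list mean of 0.07 (4 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.0509). In the p53 and DNA damage list TP53I3 (0.30), MDM2 (0.45) and TNFRSF10B (0.17) were among 4 of 18 that rose and DDB2 (-0.20) among 2 that fell, against 4 and 4 when adjusted over the list alone. That list had a mean of 0.06 and a median of -0.01 (camera adjusted p = 0.758). For SOS1, MCL1 and TNFRSF10B, 1 kept probe set had the opposite sign.

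Lipid and metabolic genes went both ways. ABCA1, the cholesterol efflux transporter, rose by 0.56 ± 0.14 (limma adjusted p = 0.0113), whereas APOE fell by 0.25, in a list of 8 with a mean of 0.09 (2 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.503). The cholesterol synthesis genes LSS (-0.33) and MVD (-0.16) fell among 10 members (list mean -0.01, camera adjusted p = 0.518). ADIPOR1 (-0.64), RPTOR (-0.24) and CPT1A (-0.33) fell among 19 insulin and metabolic genes (list mean -0.06, camera adjusted p = 0.488), and counts in both lists were the same when adjusted over the list alone. PGK1 (0.20) rose and the glucose transporter gene SLC2A1 (-0.24) fell among 21 glycolysis genes (list mean -0.0044, camera adjusted p = 0.891; 1 rose and 2 fell when adjusted over the list alone). Among 12 clock genes BMAL1 rose by 0.18 and DBP fell by 0.17 (2 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.851). JUND fell by 0.18 on 1 of its 3 kept probe sets, the others having the opposite sign, among 16 immediate early genes (1 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.735), CTSS rose among 10 MHC class II presentation genes (3 rose when adjusted over the list alone; camera adjusted p = 0.0758), and TET2 (0.42) and HDAC4 (0.18, with 2 of 3 kept probe sets in this direction) rose among 22 chromatin modifiers (2 when adjusted over the list alone; camera adjusted p = 0.461). SF3B3 (-0.16) fell among 28 spliceosome genes (0 when adjusted over the list alone; camera adjusted p = 0.503), and none of 18 heat shock and unfolded protein response genes passed (camera adjusted p = 0.735).

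Farmworker samples were spread more widely on the first component, with an SD 2.53 times that of manual workers (permutation p = 0.011 for the difference in absolute deviation, adjusted p = 0.118 over 11 measures). Across genes, the median SD ratio was 1.15 and 67.3% of genes had a higher SD in farmworkers, which a permutation of residuals did not separate from chance (p = 0.222 over 1000 permutations).

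A hypothesis was that the group difference is the erythroid variation already present among manual workers. The erythroid score was lower in farmworkers. Genes that rise with the score among manual workers would then be lower in farmworkers, which would give a negative r. Across 12263 genes outside the erythroid list, which are not independent replicates, the slope on the score within manual workers had r = -0.051 with the group log2 fold change (-0.20 to 0.06 with any 1 manual worker left out). Within farmworkers r was -0.698 (-0.718 to -0.667). The samples of both groups also enter the fold change. Whether the hypothesis holds stays open, since the manual workers varied less on the erythroid score (SD 0.516 against 1.01), though their values gave no sign of it.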
